A study of Mus musculus with 1829 samples.

How the data were processed

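CD4+ T cells of NOD/ShiLtJ mice were stained with IAg7 tetramers of insulin B chain residues 12-20 or 13-21, sorted singly into wells, and assayed on 96 by 96 chips with EvaGreen chemistry, per the labels. The values are Ct, the cycle at which an assay crossed its threshold, as exported in the deposited tables, 1 per chip. Per the file headers the export software was Fluidigm Real-Time PCR Analysis, version 4.0.1, with a quality threshold of 0.65, a linear derivative baseline and 1 automatic threshold per chip. Each value came with a pass or fail call. The labels name a toolset and custom scripts for later steps, whose versions are not given in the sources used here; the exported tables precede those steps. The chips held 2112 wells, of which 1829 matched the samples by name and 283 did not and were not used. Of 175584 Ct values, 34430 were called pass, 34030 of them under cycle 24, and 20984 values under cycle 24 were called fail.

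Ct was turned into log2Ex, 24 minus Ct, with 0 where Ct was 24 or more or the call was fail. No reference gene scaling was applied, and a difference in log2Ex between unit means holds both detection and level, so it is not a fold change. Depth is the number of assays detected per well, and the number of wells behind a share sets its precision. Intervals for shares of wells are exact Clopper-Pearson at 95%, a count of 0 allows up to 3 counts, and both cover counting error only, since wells of an animal are not independent.

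Of 96 assays, 95 were matched to mouse symbols by name or synonym (Pd1 to Pdcd1, Nur77 to Nr4a1, Pdl-1 to Cd274). The assay named Stat5 matched Stat5a as its synonym and need not be specific to it, and Il-12rb matched no single symbol and keeps its assay name. No genome positions are given, as amplicon sequences were not used here.

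Cells are not replicates. The unit was the mean log2Ex over the cells of 1 animal or lettered sort, tissue, tetramer and age on 1 chip, with at least 5 cells. Animals were named from the labels. Whether the lettered sorts were single animals is not stated, so they are called sorts. Islet sorts i1 to i4 were kept apart from animals of the same number, and merging them was an alternative. Separate blood samples of the 7-week animals M1 and M2 and the 8-week animal M3 were also kept apart from animals of the same age and number. The blood comparisons treat these as different animals, which was not tested. For 6 cells the tetramer given in the labels contradicted their title, and they entered no comparison.

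Comparisons were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), on genes detected in at least 5% of cells of either group, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. Comparisons of tetramers within a tissue and of islets with lymph node had the animal as a fixed block, lymph node against spleen the chip, and 13 against 7 weeks the animal as a random block with the tetramer as a term. Blood comparisons had no block, although the separate 8-week blood samples of M1 and M2 shared a chip, as did those of M3 and M4. Pairs came from the animal in the labels, and both arms of a pair lay on the same chip. The median correlation of paired units, each gene centred, was 0.769 for the tetramers in islets (-0.135 between animals), 0.383 in lymph node, 0.467 and 0.589 for islets with lymph node in 12-20 and 13-21 cells, and 0.415 for lymph node with spleen. In wells with at least 20 assays the first 4 were 0.630, 0.202, 0.179 and 0.165. Tables were read with Python 3.11.15 and pandas 2.3.3 and figures drawn with matplotlib 3.10.9.

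Comparisons, gene lists, named genes and most alternatives were set before the data were examined. The text names genes with an adjusted p under 0.05 in order of difference, up to 15 in each direction, and these index genes whatever their p: Ifng, Tbx21, Foxp3, Il10, Il21, Bcl6, Pdcd1, Ctla4, Icos, Ccr7, Cd44, Cxcr3 and Il2. Further index genes had no assay. Some genes that this rule selects are not reported here. Few genes outside this rule are named, each so marked or as a member of a list. Lists with at least 3 tested genes were tested with limma's fry, a rotation test of whether a list's genes move one way on balance, adjusted over the lists of a comparison. These lists, with the number of genes on the panel, were Th1 and effector (9), Th2 (5), regulatory T cell (3), follicular helper (4), activation and memory (6), chemokine receptor (8) and T cell identity (3). Interferon-stimulated (14), antigen-presenting cell and co-stimulatory ligand (6) and signalling (16) were defined after the assay names were seen. The Th17 list (3) had fewer than 3 tested genes in every comparison. Lists of inhibitory receptors (2), naive and central memory genes (2), reference genes (2) and survival genes (1) were too short to test, and the list of cytotoxic genes had 0 assays. Of the genes listed as markers of other cells, Cd8a alone was on the panel. The lists for B, myeloid, NK, gamma-delta T and islet endocrine cells had 0 assays. The antigen-presenting cell list was not among these.

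Alternatives were detection limits of 22 and 26 cycles, calls ignored, shares of cells detected in place of mean log2Ex, at least 3 or 10 cells per unit, no gene filter, units centred on their mean over the genes tested, weights by cell number, removal of cells detecting fewer than 50% of their chip's median number of assays, no block, and each animal or sort left out in turn. Centring in effect takes the mean difference of all genes tested off each gene's difference. A gene that did not change can then pass as lower where most genes rose, and a list median can turn. The filter to wells with at least 20 assays, with 15 and 25 assays as its own alternatives, was added after the number of assays per well was seen. Lymph node against spleen and the comparisons of the lettered sorts could not be fitted under it. Single-value comparisons used exact permutation tests, two-sided, or permutation tests for larger groups.

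The fits were tested on simulated data in which 10 genes were shifted, 10 runs each. The data were the real unit means with group labels redrawn, and the shift was added whole to each unit mean of 1 group. Wells with at least 20 assays averaged 37.4% of 12-20 and 37.8% of 13-21 islet units. A difference between cells would move the mean less in units with few such wells, so recovery over all wells may be overstated. For islets against lymph node of 12-20 cells, wells with at least 20 assays, 94.8% of genes shifted by 4 and 26.8% of genes shifted by 2 were recovered, with 0.1 false calls per run; over all wells false calls were 2.1 per run, the most of any comparison, with 1.8 for lymph node against spleen and 1.6 for 12 against 6 weeks. For the tetramers in islets, 91.0% of genes shifted by 2 were recovered over all wells and 98.0% of genes shifted by 4 in wells with at least 20 assays. For 13 against 7 weeks in islets, 60.4% of genes shifted by 4 were recovered over all wells, and in wells with at least 20 assays 66.0% (1.1 false calls per run) and 1.0% of genes shifted by 2.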

Results

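The series holds 1829 CD4+ T cells of NOD/ShiLtJ mice, a strain that develops autoimmune diabetes spontaneously, each sorted with a tetramer of IAg7, the class II molecule of the strain. The tetramers carried 1 of 2 overlapping peptides of the B chain of insulin, an islet antigen: residues 12-20, or residues 13-21. Transcripts were measured in each cell by quantitative PCR with 96 assays on 22 chips. By tissue, 712 cells came from lymph node, 493 from islets, 325 from spleen and 293 from blood, and 6 cells with contradicting labels were in no group. From islets, 12-20 cells numbered 171 at 7 weeks of age, 23 at 8 weeks and 70 at 13 weeks, and 13-21 cells numbered 157 at 7 weeks and 72 at 13 weeks. From lymph node, 12-20 cells numbered 85, 101, 21, 88 and 72 at 6, 7, 8, 12 and 13 weeks, and 13-21 cells numbered 85, 103, 87 and 70 at 6, 7, 12 and 13 weeks. From spleen, 12-20 cells numbered 87, 21 and 87 at 6, 8 and 12 weeks, and 13-21 cells numbered 87 and 43 at 6 and 12 weeks. Blood held 12-20 cells alone, 85 at 7 weeks and 208 at 8 weeks. Expression is given as log2Ex, the number of cycles by which a transcript crossed the threshold before cycle 24, with 0 for a transcript not detected. A unit is the mean over the cells of 1 tissue and 1 tetramer of 1 animal or sort, so that a difference in log2Ex holds both the share of cells with the transcript and its level in them.

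The T cell transcripts Cd4 and Cd3e, which encode the co-receptor by which the cells were sorted and a chain of the T cell receptor complex, were found in a minority of wells. Of the 1829 wells, 550 (30.1%) detected at least 20 assays, with a median of 41, and 1279 detected fewer, with a median of 10. Wells with 15 to 24 assays numbered 55 (3.01%). Cd4 was detected in 500 of the 550 wells (90.9%, exact Clopper-Pearson 95% interval 88.2 to 93.2%) and in 19 of the 1279 (1.49%, 0.897 to 2.31%), and Cd3e in 476 (86.5%, 83.4 to 89.3%) and 23 (1.80%, 1.14 to 2.69%). Cd8a, the co-receptor of CD8 T cells, was the 1 assay on the panel from the lists of markers of other cells. It was detected in 6 of the 550 wells (1.09%, 0.401 to 2.36%) and 1 of the 1279 (0.0782%, 0.00198 to 0.435%). Of the separate antigen-presenting cell list, Cd86 was detected in 15.6%, Cd80 in 9.64% and Cd40 in 5.82% of the 550 wells. In the 1279 these were 1.41%, 0.391% and 1.49%. In the 1279 wells with fewer than 20 assays, 10 assays were each detected in 65.4 to 99.8% of wells: Gapdh, Ifit3, Isg15, Ccr6, Ccr2, Ifi44, Cxcl10, Il25, Gsk3a and Bcl2.

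**Figure D1:**
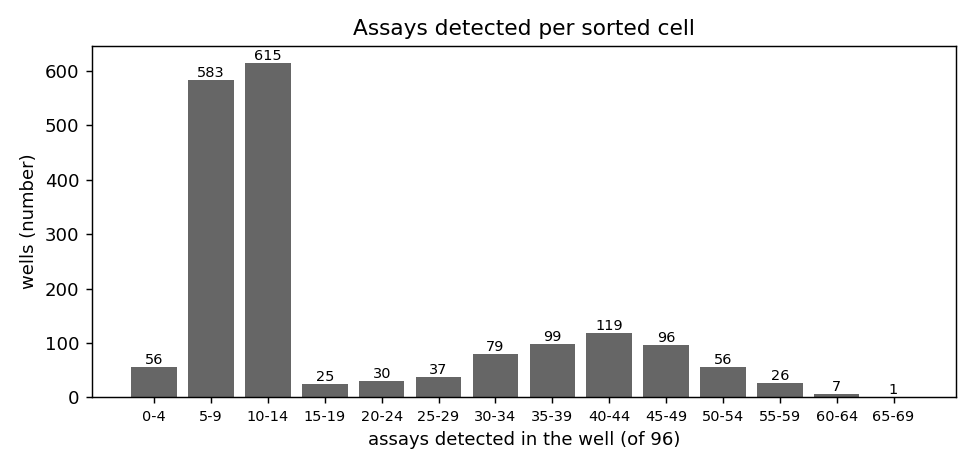
Number of wells (y axis) by the number of assays detected in the well, in steps of 5 (x axis), for all 1829 cells. The wells form a peak with a median of 10 assays and another with a median of 41, with 55 wells between 15 and 24 assays.

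The share of wells with at least 20 assays differed between chips, and tissues were spread unevenly over the chips. Pooled over chips it was 43.6% in islets (39.2 to 48.1%), 30.6% in lymph node (27.2 to 34.1%), 30.4% in blood (25.2 to 35.99%) and 8.31% in spleen (5.55 to 11.9%), intervals that cover counting error only. On the 8 chips with both tissues of the lettered sorts, lymph node had the lower mean share, 5.26% ± 6.26 against 8.996% ± 15.2 in spleen (SD, n = 8; exact permutation, adjusted p = 0.917). It ran from 0 of 61 wells (which allows a share of up to 4.92%) and 0 of 68 wells (up to 4.41%) to 89.9% of 69 wells between chips. Among 11 comparisons of this share between units, none passed 0.05 after Benjamini-Hochberg adjustment (exact permutation tests, two-sided). The smallest raw p was 0.0286, the smallest that 4 against 4 sorts can give, for 13-21 sorts of spleen and lymph node at 12.8% ± 8.80 (SD, n = 4) against 12-20 sorts at 1.44% ± 0.590 (SD, n = 4; adjusted p = 0.229, exact permutation). Islets at 13 weeks had 73.4% ± 34.7 (SD, n = 6 units) and at 7 weeks 24.2% ± 34.1 (SD, n = 16 units; permutation p = 0.0545, adjusted p = 0.229). Comparisons are therefore given over all wells, as designed, and, except for those of the lettered sorts, again over wells with at least 20 assays, a filter chosen after the number of assays per well had been seen.

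**Figure D2:**
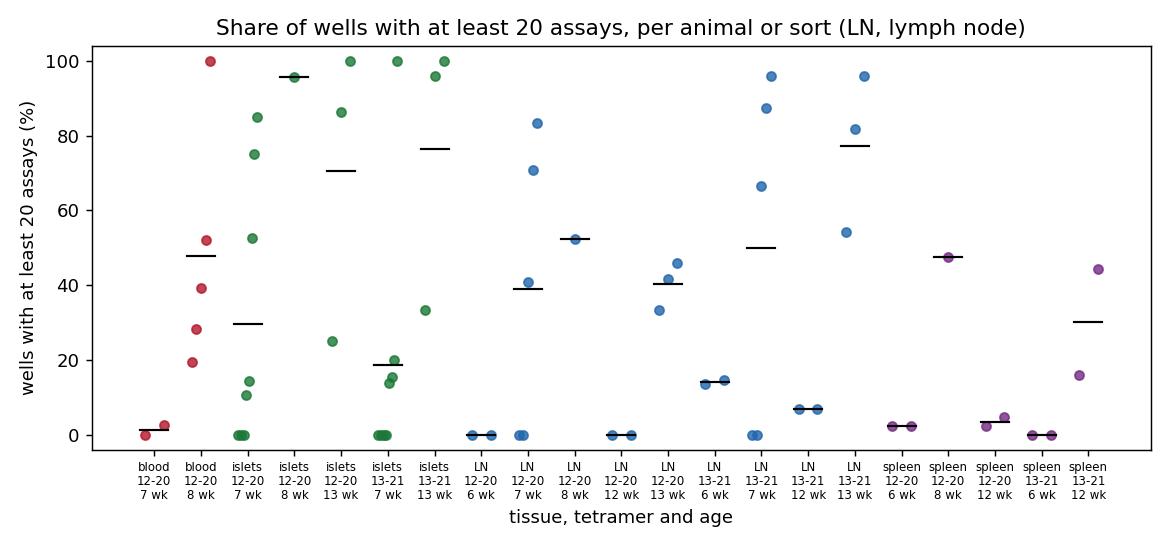
Share of wells with at least 20 assays, in percent (y axis), for each tissue, tetramer and age (x axis). Each point is 1 animal or sort with at least 5 cells and each bar the mean of the group; 7-week islets of 13-21 cells hold 1 unit at 100% with the next at 20%.

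Islet 12-20 cells had higher levels of 6 of 8 Th1 and effector genes and 4 of 6 activation genes than lymph node 12-20 cells of the same animals in wells with at least 20 assays (88 and 57 cells of 5 animals), but islet wells also detected more assays. Among 20 pairs of wells matched on the number of assays, Icos differed by -0.97 ± 1.65, Pdcd1 by -0.78 ± 3.16, Cxcr3 by -0.08 ± 2.64, Bcl6 by -0.17 ± 0.38, Ctla4 by 1.17 ± 4.45 and Ifng by 1.07 ± 2.01 (SD, n = 5 animals). In these pairs Icos was above 0 in 2 of 5 animals, Ctla4 in 3 and Ifng in 2. The values that follow are unmatched. Icos, a co-stimulatory receptor of activated T cells, averaged 7.80 ± 1.32 in islets and 3.53 ± 1.28 in lymph node (SD, n = 5). The difference was 4.27 (SE 0.718, adjusted p = 0.00514), seen in 5 of 5 animals. Ctla4, an inhibitory receptor, was higher by 4.78 (SE 1.23, adjusted p = 0.0123, 4 of 5 animals). It was detected in 69.2% ± 27.96 of islet wells and 30.6% ± 14.9 of lymph node wells. Ifng, the signature cytokine of Th1 cells, was higher by 3.44 (SE 0.845, adjusted p = 0.0110, 5 of 5 animals), detected in 42.2% ± 19.5 against 5.99% ± 8.51. Il7r, the receptor for the survival cytokine IL-7, was lower, with a difference of -3.31 (SE 0.63, adjusted p = 0.00562). Ccr7, which guides T cells into lymph nodes, was lower as well, with a difference of -3.22 (SE 0.657, adjusted p = 0.00618), each in 5 of 5 animals. The largest difference was that of Tnfrsf1b, a receptor for tumour necrosis factor, at 5.59 (SE 0.608, adjusted p = 0.000482).

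By gene list, 6 of 8 tested Th1 and effector genes rose and 2 did not pass (6 adjusted over the list alone; fry adjusted p = 0.0152). Among them were the chemokine receptor gene Cxcr3 at 3.77 (SE 1.18) and Tbx21, the Th1 master regulator, at 2.46 (SE 0.872). Of 4 follicular helper genes 3 rose and 1 did not pass (3 adjusted over the list alone; fry adjusted p = 0.0152). These were Icos, the inhibitory receptor gene Pdcd1 at 3.79 (SE 1.15) and the transcription factor gene Bcl6 at 2.54 (SE 0.615), while Il21 stood at 1.27 (SE 0.737, adjusted p = 0.161). Of 6 activation and memory genes 4 rose and 2 did not pass (5 adjusted over the list alone; fry adjusted p = 0.0154), among them Irf4 at 3.79 (SE 0.724) and the adhesion receptor gene Cd44 at 1.71 (SE 0.612). Of 3 regulatory T cell genes 2 rose and 1 did not pass (3 adjusted over the list alone; fry adjusted p = 0.0428). They were Il10, an anti-inflammatory cytokine, at 3.13 (SE 0.697) and Foxp3, the defining factor of regulatory T cells, at 2.83 (SE 1.04, adjusted p = 0.0459, 4 of 5 animals). In matched wells Il10 differed by 2.33 ± 2.70 and Foxp3 by 1.39 ± 4.73 (SD, n = 5), above 0 in 3 and 2 animals.

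Of 8 chemokine receptor genes 2 rose, among them Cxcr3, and Ccr7 fell (3 adjusted over the list alone; fry adjusted p = 0.0397). Of 3 Th2 genes Irf4 alone rose (1 adjusted over the list alone; fry adjusted p = 0.0301), and of 3 T cell identity genes 1 rose (1 adjusted over the list alone; fry adjusted p = 0.145). The remaining lists were defined after the assay names were seen. There, 10 of 15 signalling genes rose (fry adjusted p = 0.0152), as did 4 of 12 interferon-stimulated genes (fry adjusted p = 0.0329). Of 5 antigen-presenting cell genes 2 rose, Cd274, which encodes the ligand of Pdcd1, at 3.97 (SE 1.18) and the adhesion gene Icam1 at 3.44 (SE 0.629); the list had a fry adjusted p of 0.0428.

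In all, 38 genes were higher and 3 lower of 78 tested in these wells (limma, n = 5 animals). Over all wells 0 of 74 passed, with 20 at an unadjusted p under 0.05 (limma, n = 8 animals); Icos stood at 2.73 (SE 0.985), and after centring 0 genes were higher and 2 lower. Islet wells with at least 20 assays detected 46.8 ± 2.95 assays and lymph node wells 34.9 ± 1.99 (SD, n = 5; exact permutation p = 0.0625, two-sided, the smallest that 5 pairs can give). The median difference of all genes was 1.85, and the mean, which centring takes off every gene, was 1.76. After each unit was centred on its mean, 2 genes were higher, Tnfrsf1b at 3.83 (SE 0.489) and Aim2 at 1.64 (SE 0.362). In wells matched on the number of assays, Tnfrsf1b differed by 0.62 ± 4.34 and Aim2 by 0.27 ± 5.28 (SD, n = 5 animals). Centring left 5 genes lower, among them Il7r at -5.07 (SE 0.565), Ccr7 at -4.98 (SE 0.689) and Cxcl10 at -3.65 (SE 0.677). The direction of Cxcl10 is open, as before centring it was -1.89 (SE 0.707) and turned to 0.75 (SE 0.701) with calls ignored. Icos at 2.51 (SE 0.669), Ctla4 at 3.02 (SE 1.31), Ifng at 1.68 (SE 0.952) and Foxp3 at 1.07 (SE 1.02) no longer passed, and Cd44 turned to -0.0513 (SE 0.405). No list passed after centring, and the medians of the Th2, chemokine receptor, T cell identity and interferon-stimulated lists turned to -1.25, -0.18, -0.11 and -0.93. The 41 genes became 1 with at least 10 cells per unit, 27 with shares of cells detected, 25 without the 13-week animal M2 and 18 without the 13-week animal M3.

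**Figure D3:**
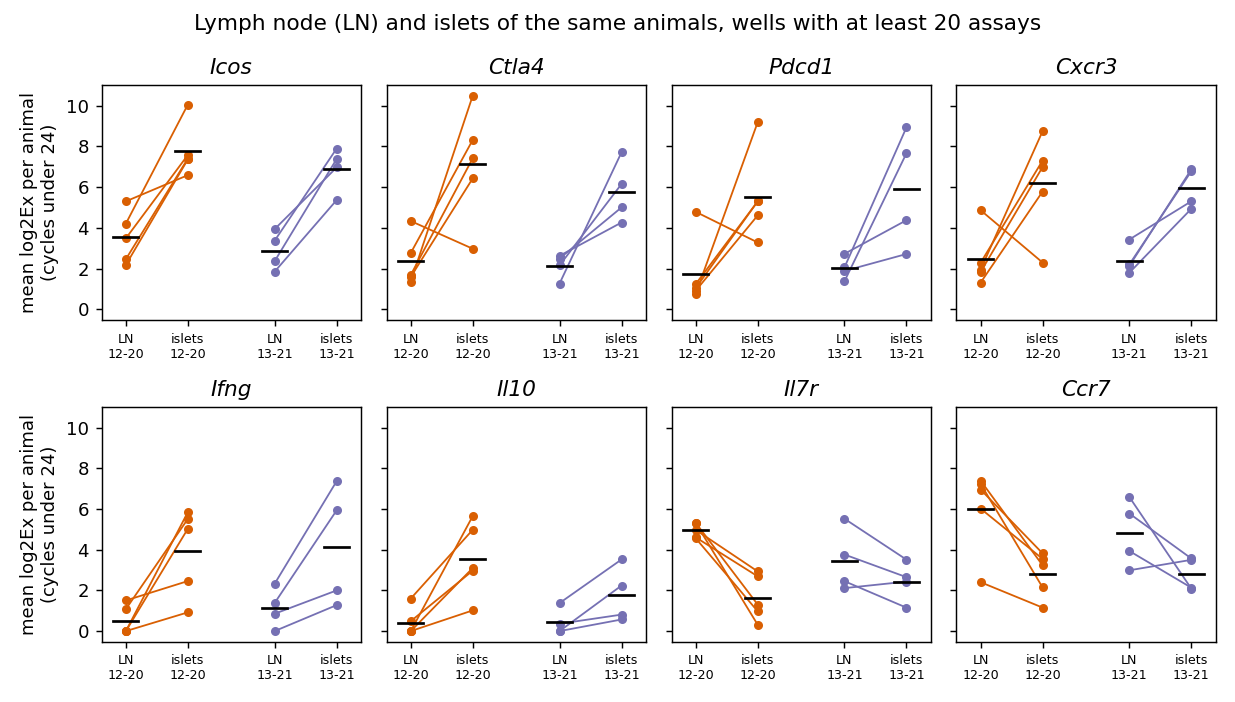
Mean log2Ex (y axis, cycles before cycle 24) of 8 genes in lymph node (LN) and islets of the same animals, wells with at least 20 assays, for 12-20 (orange, 5 animals) and 13-21 (purple, 4 animals). Lines join the tissues of an animal and black bars are means; Icos means are 7.80 in islets and 3.53 in lymph node for 12-20, before centring.

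The 13-21 cells, too, had higher islet levels of 6 of 8 Th1 and effector genes in wells with at least 20 assays (73 islet and 70 lymph node cells of 4 animals), where islet wells again detected more assays. Among 24 matched pairs of wells, Pdcd1 differed by -1.29 ± 5.71, Ctla4 by -1.16 ± 4.11, Cxcr3 by -0.24 ± 5.54, Cd274 by 1.80 ± 4.95, Icos by 0.65 ± 0.89 and Ifng by 1.48 ± 2.68 (SD, n = 4 animals). In these pairs Cd274 was above 0 in 2 of 4 animals, Icos in 3 and Pdcd1 in 2. The values that follow are unmatched. Cd274 was higher by 4.38 (SE 0.901, adjusted p = 0.00744), Icos by 4.02 (SE 0.821, adjusted p = 0.00744) and Pdcd1 by 3.91 (SE 1.05, adjusted p = 0.0168), each in 4 of 4 animals. Icos averaged 6.90 ± 1.09 in islets and 2.88 ± 0.95 in lymph node (SD, n = 4). Of 8 Th1 and effector genes 6 rose and 2 did not pass (6 adjusted over the list alone; fry adjusted p = 0.0339). Among them were Cxcr3 at 3.58 (SE 0.850), the inflammatory cytokine gene Tnf at 3.31 (SE 0.986) and Ifng at 3.002 (SE 0.918). Of 6 activation genes 2 rose and 4 did not pass (2 adjusted over the list alone; fry adjusted p = 0.0339), and in matched wells they went both ways, from Cd28 at -3.13 ± 2.63 to Nr4a1 at 1.34 ± 1.54 (SD, n = 4).

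Of 4 follicular helper genes 2 rose, Icos and Pdcd1 (3 adjusted over the list alone; fry adjusted p = 0.0770), with the cytokine gene Il21 at 2.68 (SE 1.11, adjusted p = 0.0885). Of 8 chemokine receptor genes 2 rose (3 adjusted over the list alone; fry adjusted p = 0.0770). None of 3 regulatory, 3 Th2 and 3 T cell identity genes passed (limma, 0 adjusted over each list alone; fry adjusted p = 0.0770, 0.371 and 0.190). Foxp3 stood at 0.47 (SE 0.810, adjusted p = 0.664), Il10 at 1.35 (SE 0.824), Tbx21 at 1.53 (SE 0.821) and Ccr7 at -2.0 (SE 0.916, adjusted p = 0.113). Of the lists defined after the assay names were seen, 5 of 15 signalling genes, 1 of 12 interferon-stimulated genes and 1 of 6 antigen-presenting cell genes rose (fry adjusted p = 0.0770, 0.0809 and 0.187).

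In all, 20 genes of 13-21 cells were higher and 0 lower of 78 (limma, n = 4 animals; 31 at an unadjusted p under 0.05). Over all wells 0 of 75 passed, with 4 at an unadjusted p under 0.05 (limma, n = 7 animals), and Pdcd1 stood at 2.05 (SE 1.14). Islet wells with at least 20 assays detected 45.2 ± 3.69 assays and lymph node wells 33.9 ± 3.64 (SD, n = 4; exact permutation p = 0.125, two-sided, the smallest possible). The median difference of all genes was 1.51, and the mean, which centring takes off every gene, was 1.61. After centring 0 genes were higher and 1 was lower, Ccr7 at -3.61 (SE 0.870), while Cd274 at 2.77 (SE 0.824) and Icos at 2.41 (SE 0.816) no longer passed. Foxp3 turned to -1.14 (SE 0.791) and Tbx21 to -0.08 (SE 0.821). The medians of the activation, Th2, regulatory, chemokine receptor, interferon-stimulated and antigen-presenting cell lists turned to -0.09, -1.59, -0.66, -0.67, -0.59 and -0.04. The 20 genes became 0 without the 13-week animal M4, 12 without the 13-week animal M2 and 11 without the 7-week animal M2. They became 12 with at least 10 cells per unit, 5 with at least 25 assays per well, 1 without the gene filter and 9 without the animal as a block.

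Blood 12-20 cells had higher levels of Th1 genes than lymph node 12-20 cells, in wells with at least 20 assays (88 cells of 5 blood units, 57 cells of 4 lymph node units). All 5 blood units were of 8 weeks of age and 3 of the 4 lymph node units of 7 weeks, so age and tissue cannot be told apart except in 1 animal of 8 weeks. Tbx21 averaged 6.26 ± 0.92 in blood and 0.53 ± 0.48 in lymph node (SD), a difference of 5.73 (SE 0.505, adjusted p = 2.84e-05). It was detected in 70.1% ± 9.94 and 7.49% ± 6.26 of wells. Cxcr3, a receptor for chemokines of inflamed tissue, was higher by 5.57 (SE 0.740) and Ifng by 4.82 (SE 0.645). Il2ra, the high-affinity interleukin-2 receptor chain, was higher by 4.80 (SE 0.665) and Tnfrsf1a, a receptor for tumour necrosis factor, by 4.35 (SE 0.412). Ccr7 was lower, at -5.02 (SE 0.509, adjusted p = 3.54e-05), detected in 19.5% ± 8.49 of blood and 80.7% ± 7.33 of lymph node wells. Cd4 was lower as well, at -2.37 (SE 0.566). Of 8 Th1 and effector genes 6 rose and 2 did not pass (6 adjusted over the list alone; fry adjusted p = 0.00196, and 0.00751 after centring).

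Of 7 chemokine receptor genes 3 rose, among them Cxcr3, and Ccr7 fell (4 adjusted over the list alone; fry adjusted p = 0.245). Il2ra was the 1 of 3 regulatory genes that rose (1 adjusted over the list alone; fry adjusted p = 0.203); the list's median was -0.48 and its mean 1.27. Il2ra was also the 1 of 6 activation genes that rose (1 adjusted over the list alone; fry adjusted p = 0.203). None of 4 follicular helper genes passed (limma, 0 adjusted over the list alone; fry adjusted p = 0.942), with Icos at 2.47 (SE 1.03, adjusted p = 0.0993); the list's median was -0.14 and its mean 0.42. Of 3 T cell identity genes Zap70 rose and Cd4 fell (2 adjusted over the list alone; fry adjusted p = 0.798), and 0 of 4 Th2 genes passed (limma, 0 adjusted over the list alone; fry adjusted p = 0.245). Of the lists defined after the assay names were seen, 7 of 15 signalling genes rose (fry adjusted p = 0.00846) and 0 of 11 interferon-stimulated genes passed (limma, fry adjusted p = 0.203).

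In all, 20 genes were higher in blood and 2 lower of 71 (limma, 30 at an unadjusted p under 0.05). Over all wells 0 of 63 passed, with 4 at an unadjusted p under 0.05 (limma, 7 blood and 6 lymph node units), Tbx21 stood at 1.79 (SE 0.731), and after centring 0 genes were higher and 1 lower. Blood wells with at least 20 assays detected 41.1 ± 1.45 assays and lymph node wells 33.8 ± 2.98 (SD, n = 5 and 4), and the median difference of all genes was 0.64. After centring 9 genes were higher and 13 lower, with Tbx21 at 4.65 (SE 0.515), Cxcr3 at 4.49 (SE 0.646), Ifng at 3.74 (SE 0.612) and Ccr7 at -6.10 (SE 0.447). Ctla4 at -2.46 (SE 0.469), Foxp3 at -1.59 (SE 0.380) and Pdcd1 at -1.61 (SE 0.404) passed as lower only after centring. The mean difference of all genes, which centring takes off every gene, was 1.08. These 3 genes are thus lower relative to that mean, and did not pass as lower in themselves. The medians of the Th2, activation, chemokine receptor, T cell identity and interferon-stimulated lists turned to -0.59, -0.70, -0.64, -0.94 and -0.58. Blood lay on other chips than lymph node except in an 8-week animal with all 4 tissues on 1 chip. The other 8-week blood units shared chips in pairs, which the fit does not take into account. Of the 22 genes called without that animal, 19 (86.4%) had the same sign within it. The 22 genes became 14 without the 7-week animal M2.

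Next to islet 12-20 cells, blood 12-20 cells had lower levels of follicular helper genes and of Ctla4, an inhibitory receptor (88 cells of 5 blood units, 65 cells of 4 islet units, wells with at least 20 assays). The 5 blood units were of 8 weeks of age and 3 of the 4 islet units of 7 weeks, so age and tissue cannot be told apart except in the same animal. Ctla4 averaged 0.76 ± 0.59 in blood and 9.24 ± 0.91 in islets (SD), a difference of -8.49 (SE 0.547, adjusted p = 2.02e-06). It was detected in 8.35% ± 6.00 and 97.4% ± 3.06 of wells. Pdcd1 differed by -8.00 (SE 1.02, adjusted p = 0.000455), Nr4a1, an immediate target of T cell receptor signalling, by -5.59 (SE 1.303) and Cd4 by -4.80 (SE 0.717). Il7r was higher in blood by 4.76 (SE 1.01, adjusted p = 0.0107) and Tnfrsf1a by 3.48 (SE 0.457). All 4 follicular helper genes fell, with 4 adjusted over the list alone and a fry adjusted p of 0.00201, and 0.000895 after centring. They were Pdcd1, Icos at -4.19 (SE 1.06), Il21 at -2.83 (SE 0.761) and Bcl6 at -2.19 (SE 0.627).

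Of 3 regulatory genes Foxp3 fell, at -3.26 (SE 1.06), and Il10 fell, at -2.65 (SE 0.708); 2 passed adjusted over the list alone, and the fry adjusted p was 0.178. Of 6 activation genes 3 fell, Nr4a1, Irf4 and Cd44 (4 adjusted over the list alone; fry adjusted p = 0.0765). Cd4 was the 1 of 3 T cell identity genes that fell (1 adjusted over the list alone; fry adjusted p = 0.0489, and 0.0138 after centring). Of 8 Th1 and effector genes 2 fell and 6 did not pass (2 adjusted over the list alone; fry adjusted p = 0.329), with Ifng at -0.94 (SE 0.699, adjusted p = 0.315) and Tbx21 at 1.498 (SE 0.783, adjusted p = 0.170). Irf4 was the 1 of 4 Th2 genes that fell (2 adjusted over the list alone; fry adjusted p = 0.529), and 0 of 7 chemokine receptor genes passed (limma, 0 adjusted over the list alone; fry adjusted p = 0.306). Of the lists defined after the assay names were seen, 1 of 15 signalling genes and 1 of 11 interferon-stimulated genes fell, and 0 of 3 antigen-presenting cell genes passed (limma, fry adjusted p = 0.189, 0.722 and 0.0765).

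In all, 2 genes were higher in blood and 17 lower of 74 (limma, 32 at an unadjusted p under 0.05). Over all wells 0 of 69 passed, with 2 at an unadjusted p under 0.05 (limma, 7 blood and 9 islet units), Ctla4 stood at -3.11 (SE 1.39), and after centring 0 genes were higher and 2 lower. Blood wells with at least 20 assays detected 41.1 ± 1.45 assays and islet wells 47.8 ± 4.73 (SD, n = 5 and 4), and the median difference of all genes was -0.94. After centring 8 genes were higher and 9 lower, with Ctla4 at -7.35 (SE 0.596), Pdcd1 at -6.86 (SE 0.700), Il7r at 5.89 (SE 0.865) and Tbx21 at 2.63 (SE 0.712). Foxp3 at -2.12 (SE 1.05), Il10, Il21 and Bcl6 no longer passed, and Ifng turned to 0.19 (SE 0.698). The mean difference of all genes, which centring takes off every gene, was -1.13. The medians of the Th2, chemokine receptor and interferon-stimulated lists turned to 0.93, 0.45 and 0.88. Of the 19 genes called without the animal with 4 tissues on 1 chip, 16 (84.2%) had the same sign within it. The 19 genes became 11 without the 7-week islet sort i2, 30 without the 7-week animal M2, and 8, 11, 12 and 12 without the 8-week blood of animals M1, M2, M3 and M4. They became 12 with at least 10 cells per unit and 8 with at least 15 assays per well.

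**Figure D4:**
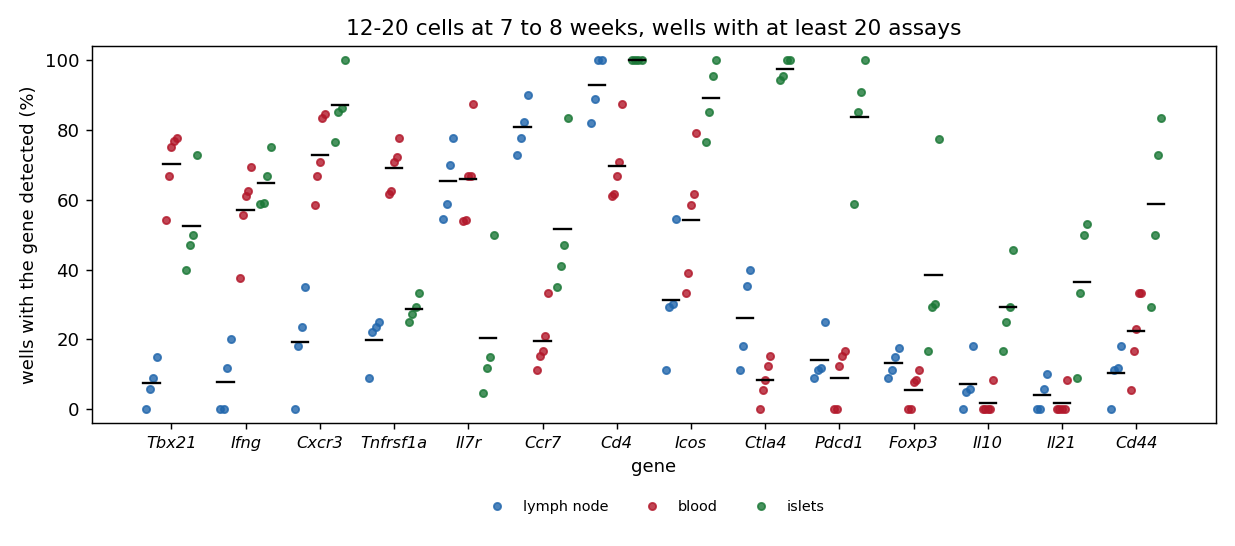
Share of wells with each of 14 genes detected, in percent (y axis), in lymph node (blue, 4 units), blood (red, 5 units) and islets (green, 4 units) of 12-20 cells, wells with at least 20 assays; blood units are of 8 weeks of age and 3 units of each other tissue of 7 weeks. Points are units and bars means; Tbx21 means are 7.49% in lymph node and 70.1% in blood, and Ctla4 means 8.35% in blood and 97.4% in islets.

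The comparison of the tetramers asks whether cells that recognise 12-20 and cells that recognise 13-21 differ in the same animal. In islets, Ifng averaged 1.81 ± 2.06 in 12-20 cells and 1.73 ± 2.68 in 13-21 cells (SD, n = 10 animals), a difference of 0.08 (SE 0.420). Foxp3 differed by 0.32 (SE 0.450) and Pdcd1 by -0.40 (SE 0.561). With at least 20 assays per well, Foxp3 differed by 1.04 (SE 0.832), Il10 by 1.02 (SE 0.688), Pdcd1 by -1.28 (SE 0.753) and Ifng by -0.43 (SE 0.584; n = 5 animals), each with an adjusted p of 0.913. No gene passed in islets, 0 of 73 over all wells (limma, 1 at an unadjusted p under 0.05) and 0 of 80 in wells with at least 20 assays (limma, 2 at an unadjusted p under 0.05). After centring 0 genes were higher and 0 lower in each, and the median difference of all genes was 0.11 and 0.13. No gene passed adjusted over any list alone. The lowest fry adjusted p of a list was 0.407 and 0.117, each for the Th2 list, whose 3 genes had a median difference of 0.28 and 0.70. Over all wells the interferon-stimulated list had a median of 0.16, a mean of -0.11 and a downward test, and the chemokine receptor list a median of 0.04 and a mean of -0.07.

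In lymph node, Icos differed by -0.76 (12-20 minus 13-21, SE 0.340, adjusted p = 0.222), Foxp3 by -0.41 (SE 0.303), Ifng by -0.34 (SE 0.270) and Ccr7 by -0.64 (SE 0.605) over all wells (n = 8 animals). With at least 20 assays per well, Ccr7 differed by 1.07 (SE 0.815, adjusted p = 0.507), Icos by -0.11 (SE 0.486) and Ifng by -0.39 (SE 0.442; n = 6 animals). No gene passed, 0 of 67 over all wells (limma, 14 at an unadjusted p under 0.05) and 0 of 72 in wells with at least 20 assays (limma, 7 at an unadjusted p under 0.05). After centring 0 genes were higher and 0 lower in each, and 0 passed adjusted over any list alone. The lowest fry adjusted p of a list was 0.0964 over all wells, and 0.187 after centring. It was 0.484 in wells with at least 20 assays, where the Th1 list had a median of 0.04 and a mean of -0.08. The median difference of all genes was -0.55 over all wells and 0.26 in wells with at least 20 assays. Centring over all wells turned the medians of the Th1, follicular helper, activation, chemokine receptor and interferon-stimulated lists to 0.02, 0.27, 0.03, 0.26 and 0.24. The share of wells with at least 20 assays was 39.5% ± 29.5 for 12-20 and 60.2% ± 39.8 for 13-21 (SD, n = 8; exact permutation p = 0.0625, two-sided, adjusted p = 0.229).

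Whether the tetramer difference depended on the tissue or the age was tested as an interaction. For tissue, Foxp3 differed by 0.75 (SE 0.717), Il10 by 0.56 (SE 0.558) and Pdcd1 by -0.68 (SE 1.25) over all wells (n = 7 animals). There 0 of 76 genes passed (limma, 2 at an unadjusted p under 0.05). Where wells had at least 20 assays, Il10 differed by 1.71 (SE 1.03; n = 4 animals), and 0 of 79 passed (limma, 0 at an unadjusted p under 0.05). For age in islets, Ctla4 differed by -2.22 (SE 1.04) and Ccr7 by -1.61 (SE 0.563) between the 3 animals of 13 weeks and the 7 of 7 weeks. There 0 of 81 genes passed (limma, 2 at an unadjusted p under 0.05), and 1 passed without the 13-week animal M2. With at least 20 assays per well 0 of 83 passed (limma, 3 at an unadjusted p under 0.05; 3 against 2 animals). After centring 0 genes were higher and 0 lower in each of these 4 fits, and no list passed, with a lowest fry adjusted p of 0.131.

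Spleen and lymph node of the lettered sorts held 12-20 or 13-21 cells of 6 and 12 weeks on separate chips. Over all wells, T cell and signalling genes differed between the tetramers (302 and 347 cells, 4 against 4 sorts). Wells with at least 20 assays made up 12.8% ± 8.80 of the 13-21 sorts and 1.44% ± 0.590 of the 12-20 sorts (SD, n = 4, exact permutation, adjusted p = 0.229). Differences over all wells hold this difference in share too. Cd4 averaged 1.48 ± 0.60 in 13-21 sorts and 0.13 ± 0.06 in 12-20 sorts (SD, n = 4), a difference of 1.35 (SE 0.224, adjusted p = 0.00823). It was detected in 14.97% ± 7.39 and 1.72% ± 0.664 of wells. Over the series Cd4 was detected in 90.9% of wells with at least 20 assays and 1.49% of others, so its share followed theirs. Tgfbr2, a receptor chain for transforming growth factor beta, was higher by 1.51 (SE 0.283). Cxcl10 differed by -1.304 (SE 0.362), Ccr6 by -1.29 (SE 0.293), Il25 by -1.19 (SE 0.232) and Gapdh by -0.41 (SE 0.148), all among the assays detected in most wells.

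The lists were tested over all wells, so they too hold the difference in the share of wells with at least 20 assays. Of 3 T cell identity genes 3 rose, Cd4, Cd3e and Zap70 (3 adjusted over the list alone; fry adjusted p = 0.00214, and 0.222 after centring). Of 4 activation genes 2 rose and 2 did not pass (2 adjusted over the list alone; fry adjusted p = 0.00602, and 0.217 after centring). Of 3 chemokine receptor genes 1 rose and 1 fell, Ccr6 (2 adjusted over the list alone; fry adjusted p = 0.263). Of the lists defined after the assay names were seen, 11 of 13 signalling genes rose and 2 did not pass (fry adjusted p = 0.00214, and 0.205 after centring). There, too, 3 of 7 interferon-stimulated genes rose and 2 fell (fry adjusted p = 0.288), and 1 of 3 antigen-presenting cell genes rose, Icam1 (fry adjusted p = 0.107).

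In all, 26 genes of the lettered sorts were higher and 6 lower of 48 (limma), and the median difference was 0.67. The mean difference, which centring takes off every gene, was 0.49. After centring 7 genes were higher, among them Cd4 at 0.85 (SE 0.183), and 9 were lower. Wells with at least 20 assays made up 12.8% ± 8.80 of the 13-21 sorts and 1.44% ± 0.590 of the 12-20 sorts (SD, n = 4), and without these wells 1 gene of 13 passed. The 32 genes became 0 with spleen alone and 20 with Ct values read without the pass or fail call. In that reading Irf1 turned to -0.52, Icam1 to -0.87, Ly6e to -0.40, Nfkb1 to -0.80 and Vav1 to -0.53. They became 15 without sort A and 16 without sort B of 12-20 at 12 weeks, and 20 without sort B of 12-20 at 6 weeks. Tetramer and chip cannot be told apart in these sorts, and a fit on wells with at least 20 assays could not be fitted.

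In the same sorts, Ifngr1, a chain of the interferon gamma receptor, differed by 0.87 (SE 0.358), Tgfbr2 by 0.73 (SE 0.305) and Il25 by -0.87 (SE 0.278) between 12 and 6 weeks (n = 4 and 4). Each had an adjusted p of 0.231 and was named after its values were seen. Of 36 genes 0 passed (limma, 3 at an unadjusted p under 0.05), 0 adjusted over any list alone, and 0 were higher and 0 lower after centring. The lists with 3 tested genes were activation, signalling and interferon-stimulated, with fry adjusted p of 0.143, 0.241 and 0.821; the median of all genes was 0.42, and centring turned the median of the last list to -0.20. Between lymph node and spleen on the 8 chips, Isg15, an interferon-stimulated gene, differed by 0.67 (SE 0.385) and Ccr3, a chemokine receptor, by -0.997 (SE 0.512). The adjusted p was 0.837 for each, and both were named after the values were seen. Of 29 genes 0 passed (limma, 0 at an unadjusted p under 0.05), 0 were higher and 0 lower after centring, and the median difference was -0.11. The interferon-stimulated and signalling lists had fry adjusted p of 0.433 and 0.734.

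Between 7 and 13 weeks of age, single genes differed in islet cells over all wells, and no gene list passed after centring. Il4ra, the receptor for interleukin 4, was higher at 13 weeks by 3.22 (SE 0.776, adjusted p = 0.0242), detected in 48.2% ± 19.1 of wells against 9.22% ± 13.8 (SD, n = 6 and 16 units). Tnfaip3, an inhibitor of NF-kappaB signalling, was higher by 5.65 (SE 1.99). Cxcr4, a chemokine receptor, was higher by 5.07 (SE 1.46) and Socs3, an inhibitor of cytokine signalling, by 3.07 (SE 0.763). Pdcd1 differed by 1.46 (SE 1.88, adjusted p = 0.528) and Ifng by 1.27 (SE 1.41, adjusted p = 0.477). Wells with at least 20 assays made up 73.4% ± 34.7 of the 13-week units and 24.2% ± 34.1 of the 7-week units. None of these genes passed in such wells (limma, 6 and 5 units), with Pdcd1 at -4.66 (SE 1.35, adjusted p = 0.124) and Ifng at -3.56 (SE 1.21, adjusted p = 0.128).

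Over all wells Il4ra was the 1 of 3 Th2 genes that rose (1 adjusted over the list alone; fry adjusted p = 0.0490). Of 8 Th1 genes 2 rose (2 adjusted over the list alone; fry adjusted p = 0.177), and of 8 chemokine receptor genes 2 rose (2 adjusted over the list alone; fry adjusted p = 0.119). Nfkb1 was the 1 of 6 activation genes that rose (0 adjusted over the list alone; fry adjusted p = 0.177). None of 3 regulatory, 4 follicular helper and 3 T cell identity genes passed (limma, 0 adjusted over each list alone; fry adjusted p = 0.177, 0.177 and 0.164). Of the lists defined after the assay names were seen, 5 of 6 antigen-presenting cell genes rose, among them Cd274 at 3.98 (SE 1.26), with a fry adjusted p of 0.00209. There, too, 5 of 15 signalling genes rose (fry adjusted p = 0.0490), as did 3 of 12 interferon-stimulated genes (fry adjusted p = 0.0350).

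In all, 19 genes were higher at 13 weeks and 0 lower of 79 (limma, 35 at an unadjusted p under 0.05), and the median difference was 1.82. The mean difference, which centring takes off every gene, was 2.11. After centring 9 were higher, among them Cxcr4 at 2.96 (SE 0.720), 2 were lower, and no list passed. Centring turned the medians of the Th2, Th1, chemokine receptor, activation, antigen-presenting cell and interferon-stimulated lists to -0.62, -0.59, -0.78, -0.61, -0.11 and -1.21, and those of the regulatory and follicular helper lists to -0.92 and -0.38. With at least 20 assays per well 0 of 79 passed (limma, 20 at an unadjusted p under 0.05), and the median difference was 0.22. After centring 4 were higher there and 6 lower, among them Pdcd1 at -4.56 (SE 1.13) and Il4ra at 3.21 (SE 0.780). Of 8 Th1 genes 6 passed adjusted over the list alone, with a list median of -3.03 (fry adjusted p = 0.103, and 0.0154 after centring). After centring the T cell identity list passed too, with a median of -2.78 (fry adjusted p = 0.0453), as did the antigen-presenting cell list at 2.56 and the Th2 list (fry adjusted p = 0.0154 for each). The Th2 list had a median of -0.36, a mean of 0.27 and an upward test, and the chemokine receptor list a median of -0.72 and a mean of 0.09.

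The 19 genes depended on single animals: they became 39, 6 and 0 without the 13-week animals M2, M3 and M4, and 45, 34, 6, 0 and 6 without the 7-week animals M1, M2, M7, M10 and M11. They became 8, 3, 6 and 8 without the 7-week islet sorts i1, i2, i3 and i4. Settings moved them too, to 0 with at least 3 cells per unit, 30 with at least 10, 30 with shares of cells detected, 37 with weights and 5 with calls ignored. They became 0 without cells that detected few assays for their chip, and 0 without the chips on which no well had 20 assays. Among wells with at least 20 assays, 15 genes passed without the 13-week animal M3 and 2 without the 7-week animal M2. Age lay on separate chips, so age and chip cannot be told apart.

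In lymph node, Icos differed by 0.73 (SE 0.746), Pdcd1 by 0.62 (SE 0.549) and Ccr7 by -0.22 (SE 1.56) between 13 and 7 weeks (n = 6 and 10 units). Of 67 genes 0 passed (limma, 0 at an unadjusted p under 0.05; lowest fry adjusted p 0.641), 0 were higher and 0 lower after centring, and the median difference was 0.72. With at least 20 assays per well, Socs3 differed by 1.94 (SE 0.4658, adjusted p = 0.0615), Tnfrsf1a by 1.62 (SE 0.426, adjusted p = 0.0638) and Ccr7 by -1.75 (SE 0.853, adjusted p = 0.372; n = 6 and 6 units). Of 72 genes 0 passed there (limma, 10 at an unadjusted p under 0.05), and the lowest fry adjusted p was 0.113. After centring 3 were higher, among them Socs3 at 1.74 (SE 0.432), and 2 lower. The chemokine receptor list had a median of 0.28 and a mean of -0.23. Without the 13-week animal M2, 1 gene passed, and 4 passed with shares of cells detected.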

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

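The tests of the detection pattern in the wells, of the lower Il7r and Ccr7, and of the other splits were chosen after the results were seen; the test on matched wells and the test within the chip with 4 tissues were not.

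In islets at 7 weeks, 100% of the 13-21 wells of animal M2 detected at least 20 assays, while the next of the 8 units stood at 20% and the lowest at 0%, a gap of 0.800 of the range. It was the 1 unit that stood apart in 15 groups tested, and chance marks about 1 in 20 groups. In 2 further animals of this group with under 5 cells each, left out of the units, 3 of 3 and 4 of 4 wells detected at least 20 assays.

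Most wells detected Gapdh, Ifit3, Isg15, Ccr6 and a few more assays and little else. A graded range of RNA content between cells is argued against by the 3.01% of wells with 15 to 24 assays. Template other than the mRNA of the cell, such as genomic DNA, may be read by these 10 assays, since their level in wells with at least 20 assays differed from that in other wells of the same chip by a median of 0.02 (0.0222 before rounding), with Gsk3a apart at 3.88 ± 0.58 (SD, 14 chips). Handling of single chips stays open: 18 of 22 chips lay outside the binomial range of the pooled share, but most chips held 1 animal, so chip and animal cannot be told apart. Shares also differed within 1 chip and animal, in both directions. In the 7-week animal M7, 0 of 24 (12-20) and 0 of 21 (13-21) islet wells detected at least 20 assays. Its lymph node had 9 of 22 and 21 of 24. The 13-week animal M3 had 24 of 24 islet wells and 8 of 24 lymph node wells of 12-20 cells. A cause shared by a whole chip or animal does not alone give these differences. Beyond the range of RNA content, no biological explanation was tested.

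Genes higher in islets than in lymph node in wells with at least 20 assays may in part reflect that islet wells read more assays of any kind. Among 20 pairs of 12-20 wells of 5 animals matched on the number of assays, the median difference of the 38 genes went from 2.95 to 0.57, which keeps 19.4%, with 26 of 38 still higher; for 13-21 it went from 3.22 to 0.62 (19.1%, 24 pairs of 4 animals, 13 of 20 still higher). The number of assays counts these genes too, so matching also removes a real difference between the tissues, which stays open and is named by the design. Lower Il7r and Ccr7 in 12-20 are harder to explain this way, as more assays per well would raise them: the smaller drop was -3.22, and matched wells gave -2.89 ± 2.83 for Ccr7 and -2.31 ± 2.52 for Il7r (SD, n = 5 animals), but -1.16 ± 2.997 and 0.65 ± 2.23 in 13-21 (SD, n = 4). Genes that turned in matched wells included Icos at -0.97, Pdcd1 at -0.78, Nfkb1 at -0.78, Cxcr3 at -0.08 and Bcl6 at -0.17 in 12-20, and Pdcd1 at -1.29, Ctla4 at -1.16, Tnfrsf1b at -0.83 and Cxcr3 at -0.24 in 13-21.

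Genes called between blood and lymph node may reflect a difference between chips or ages, since tissue followed the chip and, in wells with at least 20 assays, nearly followed age. Within the 8-week animal with its 4 tissues on 1 chip, 19 of 22 genes called without it (86.4%) had the same sign, and 16 of 19 (84.2%) for blood against islets. With 1 such animal, chip, age and tissue cannot be told apart for the sizes of the differences, and a difference between tissues stays open.

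Other splits of the same units tested whether chance can give as many genes. In wells with at least 20 assays, 1 of 100 splits, the real one, gave the 22 genes of blood against lymph node (highest other 13). For the 19 genes of blood against islets it was also 1 of 100 (highest other 5). No other split drawn gave as many. The shares were not adjusted over the comparisons, and the splits tell tissue from neither age nor chip. Blood units that shared a chip were exchanged as if separate. For the tetramers in the lettered sorts, 1 of 34 splits gave 32 genes (highest other 0), the smallest share that 34 splits can give. For 13 against 7 weeks in islets over all wells, 2 of 100 splits gave 19 or more genes. Another split of those units gave 58 genes, so chance is not excluded for that count. What the split with 58 genes separated was not tested. These shares, too, were not adjusted over the comparisons. Splits were too few for a share under 0.05 for islets against lymph node in wells with at least 20 assays, in 12-20 (1 of 16, real 41, highest other 2) and 13-21 (1 of 8, real 20, highest other 0).

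Where no gene was called, every split gives at least as many by construction, so the count says nothing about chance. Over all wells these were the tetramers in islets (100 of 100, highest other 2) and lymph node (100 of 100, highest other 1), islets against lymph node in 12-20 (100 of 100, highest other 0) and 13-21 (64 of 64, highest other 0), lymph node against spleen (100 of 100, highest other 0), 12 against 6 weeks (34 of 34, highest other 0), 13 against 7 weeks in lymph node (56 of 56, highest other 46), blood against lymph node (100 of 100, highest other 0) and islets (100 of 100, highest other 27), and the interactions with tissue (64 of 64, highest other 0) and age (100 of 100, highest other 5). What the splits with 46 and 27 genes separated was not tested. In wells with at least 20 assays it was the tetramers in lymph node (32 of 32, highest other 1). Splits were too few there for the tetramers in islets (16 of 16, real 0, highest other 0), 13 against 7 weeks in islets (10 of 10, real 0, highest other 5) and lymph node (10 of 10, real 0, highest other 0), and the interaction with tissue (8 of 8, real 0, highest other 0).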

How the results depend on the processing

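All alternatives for wells with at least 20 assays, and those that restrict the wells or chips by the number of assays, were chosen after seeing the data. Counts of 0 over all wells stayed 0 under every setting run for the tetramers in islets and lymph node, for 13-21 islets against lymph node except the filter to wells with at least 20 assays (20), for lymph node against spleen, 12 against 6 weeks, 13 against 7 weeks in lymph node and the interaction with tissue. The filter also gave 41 for 12-20 islets against lymph node, 22 for blood against lymph node and 19 for blood against islets, and centring gave 2, 1 and 2 for these comparisons. The interaction with age gave 1 without the 13-week animal M2 (left-out range 0 to 1). The causes were not tested unless named.

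The 32 genes between the tetramers in the lettered sorts became 20 with calls ignored, 16 with centring, 0 with spleen alone and 1 in wells with fewer than 20 assays, and 15 to 36 with a sort left out. With calls ignored, Ly6e turned to -0.40, Irf1 to -0.52, Icam1 to -0.87, Vav1 to -0.53 and Nfkb1 to -0.80. The 19 genes between 13 and 7 weeks in islets became 5 with calls ignored, 30 with shares of cells detected, 0 with at least 3 and 30 with at least 10 cells per unit, 11 with centring, 37 with weights, 0 without cells detecting few assays for their chip, 0 in wells with at least 20 assays, 0 without chips lacking such wells, and 0 to 45 with an animal left out.

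In wells with at least 20 assays, the 41 genes of 12-20 islets against lymph node became 27 with shares, 1 with at least 10 cells per unit (fewer units) and 7 with centring, and 18 to 43 with an animal left out; Cxcl10 turned to 0.75 with calls ignored and Cd44 to -0.0513 with centring. Without the animal as a block, limma called 34 genes in place of 41. The 20 genes of 13-21 became 12 with at least 10 cells, 1 with no gene filter (more genes tested), 1 with centring, 9 with no block, 5 with at least 25 assays per well, and 0 to 24 with an animal left out, 0 being without the 13-week animal M4. The count of 22 genes of blood against lymph node ran from 14 to 23 with a unit left out. No other setting moved the count by more than 1.5 times. Centring kept it at 22 but changed the genes, with 9 higher and 13 lower in place of 20 and 2. The 19 of blood against islets became 12 with at least 10 cells and 8 with at least 15 assays, and 8 to 30 with a unit left out. Centring gave 17 there, with 8 higher and 9 lower in place of 2 and 17. The 0 of 13 against 7 weeks became in islets 1 with shares, 2 with at least 3 cells, 10 with centring and 0 to 15 with an animal left out, and in lymph node 2 with a limit of 26 cycles, 4 with shares, 2 with no gene filter, 5 with centring, 3 with weights, 3 with at least 15 assays and 0 to 1 with an animal left out. The tetramer counts and both interactions stayed 0 in these wells under every setting run.

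A part of the genes that had passed was followed 1 by 1 under the alternatives: of 2158 values, 1591 kept their direction and side of the threshold, 560 kept their direction without passing and 7 reversed. Genes that had not passed were outside this count, and some turned, such as Foxp3 to -1.14 and Tbx21 to -0.08 with centring in 13-21 islets against lymph node. The number of assays detected per well limits what can be seen: with a median of 10 assays in 1279 wells, a transcript not detected there is not shown to be absent from the cell.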

Other observations

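The tests of pairs of genes in the same wells were chosen before their results were seen; the values of the animal with 4 tissues were chosen after.

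In the 8-week animal whose 12-20 cells of 4 tissues lay on 1 chip, wells with at least 20 assays numbered 24 from blood, 22 from islets, 11 from lymph node and 10 from spleen, and no replicate exists for this set. Foxp3, the factor that defines regulatory T cells, was detected in 77.3% of islet wells (exact Clopper-Pearson 95% interval 54.6 to 92.2%), 8.33% of blood wells (1.03 to 26.997%), 9.09% of lymph node wells (0.230 to 41.3%) and 20.0% of spleen wells (2.52 to 55.6%). Pdcd1, the inhibitory receptor PD-1, was detected in 90.9% of islet wells (70.8 to 98.9%), 12.5% of blood wells (2.66 to 32.4%) and 9.09% of lymph node wells (0.230 to 41.3%). Tbx21 was detected in 72.7% of islet wells (49.8 to 89.3%), 54.2% of blood wells (32.8 to 74.4%), 9.09% of lymph node wells and 0 of 10 spleen wells (up to 30.8% by the same method). Il7r was detected in 4.55% of islet wells (0.115 to 22.8%), 87.5% of blood wells (67.6 to 97.3%) and 54.5% of lymph node wells (23.4 to 83.3%). Ccr7 was detected in 40.9% of islet wells (20.7 to 63.6%), 33.3% of blood wells (15.6 to 55.3%), 72.7% of lymph node wells (39.03 to 94.0%) and 7 of 10 spleen wells (34.8 to 93.3%).

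Genes of the same T cell programme may be detected in the same wells more often than chance gives, and genes of different programmes less often. Over 12 animals and 493 wells with at least 20 assays, the share of wells with both genes was compared with that given by independence, 8 pairs in all. Independence was computed within each tissue and tetramer of an animal, apart for wells above and up to the median number of assays (exact sign-flip tests, two-sided, Benjamini-Hochberg adjusted; smallest raw p 0.000488). The excess was 2.99 ± 2.69 percentage points for Ifng with Tbx21 (SD, n = 12; above 0 in 11 animals; exact adjusted p = 0.00391) and 5.06 ± 3.79 for Ifng with Cxcr3 (10 animals; exact adjusted p = 0.00391), both of the Th1 programme. It was 4.96 ± 3.71 for Foxp3 with Ctla4 (10 animals; exact adjusted p = 0.00391) and 5.62 ± 3.51 for Foxp3 with Il2ra (11 animals; exact adjusted p = 0.00391), of the regulatory programme, and 2.18 ± 2.01 for Il21 with Pdcd1 (9 animals; exact adjusted p = 0.00521), of the follicular helper programme. For Foxp3 with Ifng the excess was -2.79 ± 2.64 (below 0 in 9 animals, above 0 in 0; exact adjusted p = 0.00521). Il21 with Bcl6 gave 0.740 ± 1.203 (6 animals; exact adjusted p = 0.0670) and Ccr7 with Pdcd1 -0.180 ± 2.95 (7 animals above 0; exact adjusted p = 0.834), which did not pass. A difference in the number of assays that remains within these groups of wells adds to every excess above 0.

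The 6 cells whose tetramer label contradicted their title detected 8 to 52 assays, with a median of 8.50, and 1 of them detected at least 20.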
